A study of Homo sapiens with 6 samples.

How the data were processed

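RNA-seq libraries were made from total RNA of Jurkat cells, 3 with a control shRNA (shCtrl, replicates 1 to 3) and 3 with a shRNA against SATB1 (shSATB1, replicates 1 to 3). Groups and replicate numbers were taken from the sample titles. The authors deposited 1 table of raw read counts per Ensembl gene for each library, neither normalized nor pooled. Trim Galore, STAR and HTSeq and the genome build hg38 are named, per the submitters' processing notes, without versions or settings. The annotation release, the strand setting and any selection of polyadenylated RNA are not given in the sources used here. Overlapping genes, antisense partners and near-identical copies are therefore uncertain. All 58735 gene identifiers were found in GENCODE 29, which supplied symbols, gene types and hg38 coordinates.

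Each table ends with 5 lines that name no gene, and these stayed out of library sizes and tests. Reads in no annotated exon made up 10.2%, 7.77% and 9.36% of reads in shCtrl 1, 2 and 3 and 11.7%, 10.9% and 11.6% in shSATB1 1, 2 and 3. Ambiguous reads made up 9.84% ± 0.300 (SD, n = 3) in shCtrl and 9.11% ± 0.180 in shSATB1, and reads without a unique alignment 4.34% and 4.33%. Reads in genes numbered 28435130, 28913623 and 27737353 in shCtrl 1, 2 and 3 and 26626539, 27623634 and 28143385 in shSATB1 1, 2 and 3. At this depth 3 reads correspond to 0.104 to 0.113 CPM, a floor that covers counting error only. No libraries of a group held the same values, and the chi-square per degree of freedom over genes was between 2.97 and 23.1 within groups, highest for shCtrl 1 and shCtrl 2. All 6 libraries were kept. The first principal component held 51.9% of the variance and separated the groups, and the second held 17.5%.

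Counts were tested with edgeR 4.0.16 (R 4.3.3) by TMM normalization, filterByExpr with a minimum count of 10, and the quasi-likelihood F test of shSATB1 against shCtrl without covariates. Benjamini-Hochberg adjustment ran over 17520 genes, with a threshold of 0.05. The biological coefficient of variation was 7.27%. CPM values are counts scaled to TMM-adjusted library sizes, and the fold is taken from the fitted log2 fold change. The 27 gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the lists, and with fry, which tests whether the members of a list move on balance in the same direction (16 lists under 0.05). Neighbouring genes were tested with 10000 permutations of the calls within deciles of mean log2 CPM, and gene types with Fisher's exact test. Other tools were limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.

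The tests, the gene lists, the rule for named genes and the other settings listed next were fixed before the data were examined. Named genes were SATB1, then the 10 largest rises and 10 largest falls among called genes with at least 2 CPM in the higher group, no overlap between the groups and an established symbol (1 gene was passed over among the falls). Per list, up to 4 called members with the largest change were named, or the 2 of highest CPM where fewer than 2 were called. Which of these members the text describes was decided after their values were seen, and members whose calls held with each library left out were preferred. Where 5 or fewer members of a list rose or fell, those outside the rule are named, chosen after their values were seen. For genes outside the rule, calls under other settings were not recorded. These settings were DESeq2 size factors, upper quartile normalization, no filter, a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, a replicate block, leaving out each library, a null hypothesis of a 1.2-fold change, an estimated correlation for the lists, and for neighbours 2-fold calls, pairs within 100 kb and protein-coding genes. Added after seeing the data were a correction for gene length and GC content, the share of reads in no annotated exon as a covariate (called the covariate in the results), a permutation of neighbours within bins of expression, length and GC, and for gene types a Mantel-Haenszel test within deciles of mean log2 CPM.

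The analysis was tested on simulated counts for shSATB1 against shCtrl, drawn for 17520 genes from the observed means, library sizes and dispersions, with known changes. It recovered 63.0% of 73 genes changed by 0.5 in log2, 87.1% of 70 changed by 1 and 98.2% of 57 changed by 2, with 7 false calls among 170. The simulated counts held no trend with gene length between libraries and far fewer changed genes than were called in the data. These rates therefore need not hold for the data.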

Results

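Gene expression was measured by RNA-seq in Jurkat cells, an established human T cell leukaemia line, after lentiviral delivery of a short hairpin RNA (shRNA). A control hairpin (shCtrl) was compared with a hairpin against SATB1 (shSATB1), which encodes a DNA-binding protein that organises chromatin in T cells. Each group held 3 libraries, with between 26626539 and 28913623 reads in annotated genes. The comparison asks which transcripts differ when SATB1 is lowered, in a study on how SATB1 shapes genome folding in T cells. Nothing states that the replicates were separate cultures or infections, so p-values measure only the spread between these libraries, which may be technical. At least 1 read was found for 26726 ± 324.0 genes (SD, n = 3) in shCtrl and for 27692 ± 180.7 in shSATB1.

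SATB1 (ENSG00000182568, chromosome 3, 18345387 to 18445588, minus strand, hg38) was lower in all 3 shSATB1 libraries than in all 3 shCtrl libraries. Its level fell from 265.6 ± 11.6 to 102.0 ± 1.94 CPM (counts scaled to library size; mean ± SD, n = 3 per group, as for all CPM values). Single libraries stood at 279.1, 258.5 and 259.3 CPM in shCtrl and at 101.8, 100.2 and 104.1 CPM in shSATB1, from 2796 to 7778 reads per library. The log2 fold change was -1.38 with a standard error of 0.0611 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.11e-08). This left 38.4% of the control level, with a 95% interval from 35.3% to 41.7%. A two-sided exact permutation test of the CPM values gave p = 0.1, the smallest that 3 against 3 libraries can give.

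SLC6A13, a GABA transporter gene (chromosome 12, 220621 to 262873), had the largest rise among the named genes, 6.18-fold from 1.24 ± 0.472 to 7.68 ± 0.867 CPM. SMAD7, an inhibitor of TGF-beta signalling, rose 4.49-fold from 2.12 ± 0.383 to 9.54 ± 0.353 CPM. EPAS1, which encodes the hypoxia-inducible factor HIF-2alpha, rose 3.37-fold from 6.47 ± 0.930 to 21.8 ± 1.58 CPM, and GZMA, the protease granzyme A of cytotoxic lymphocytes, rose 3.15-fold from 13.8 ± 1.54 to 43.3 ± 1.65 CPM. ECEL1, ASCL4, F13A1, HIST1H2AC, SCG2 and APOBR rose between 3.19-fold (APOBR) and 4.72-fold (ECEL1). Among the falls, DNTT had the highest control level. It encodes terminal deoxynucleotidyl transferase, which adds nucleotides at the joints of rearranging antigen receptor genes (chromosome 10, 96304396 to 96338564), and fell 3.65-fold from 344.6 ± 29.1 to 94.5 ± 3.27 CPM. Its neighbour OPALIN (chromosome 10, 96343216 to 96359365) fell 4.05-fold from 3.31 ± 0.612 to 0.814 ± 0.0290 CPM. DNTT lies on the plus strand and OPALIN beyond its end on the minus strand. The strand setting is not given, and whether reads running on from DNTT count toward OPALIN was not tested. IGLL1, part of the surrogate light chain of the pre-B cell receptor, fell 3.28-fold from 57.5 ± 6.55 to 17.5 ± 2.60 CPM. STAU1, a double-stranded RNA-binding protein gene (chromosome 20, 49113339 to 49188367), fell 3.22-fold from 176.9 ± 5.49 to 54.9 ± 1.45 CPM, and NDUFAB1, the mitochondrial acyl carrier protein gene (chromosome 16, 23581002 to 23596356), fell 3.28-fold from 108.1 ± 14.3 to 33.0 ± 1.57 CPM. SATB1 itself fell 2.60-fold. FA2H, F2RL2, COBL, MORN2 and KANK4 fell between 2.88-fold (KANK4) and 3.55-fold (FA2H). Adjusted p of these named genes lay between 2.94e-09 (STAU1) and 0.000163 (KANK4, edgeR with Benjamini-Hochberg adjustment). The 3′ untranslated regions of OPALIN, F2RL2 and F13A1 hold the sequence GAAGGAC, which also occurs at 2 places in the SATB1 mRNA. It was picked from 5373 tested 7-base sequences of that mRNA, as the one whose carriers shifted lowest in these same data. Its presence in named genes is therefore no separate evidence of an off-target effect.

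**Figure D1:**
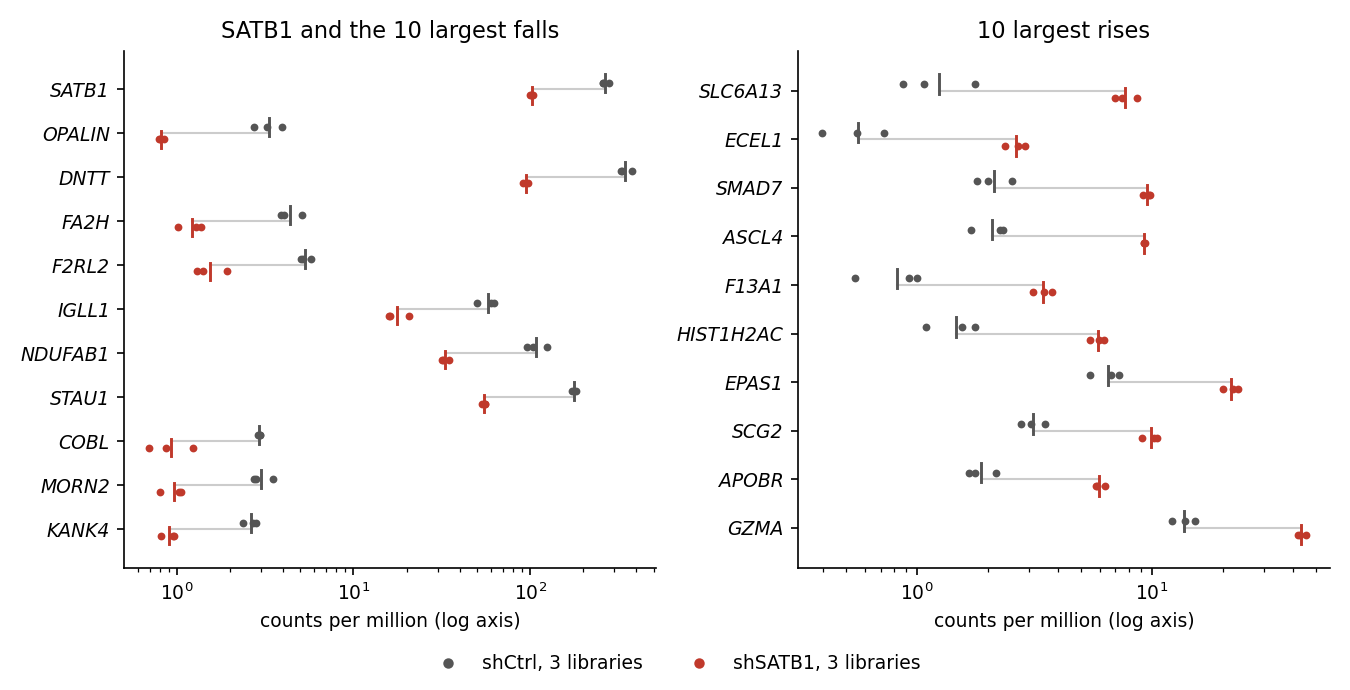
CPM (log axis) of SATB1 and the 10 named genes that fell most (left) and of the 10 named genes that rose most (right). Points are single libraries, 3 per group, and short vertical bars are group means; in each gene all libraries of shSATB1 lie on the same side of all libraries of shCtrl.

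Of 17520 genes tested, 2500 rose and 2910 fell in shSATB1 at an adjusted p under 0.05 (edgeR), and most of these changes were small. The median fold of the called genes was 1.31, and 77.1% of them changed by less than 1.5-fold. A change of 2-fold or more was found for 388 genes, of which 300 rose and 88 fell. Of these, 209 rising and 49 falling genes had a mean under 2 CPM in both groups. All libraries of shSATB1 lay on the same side of all libraries of shCtrl in 45.1% of tested genes, against 10% by chance. Fold changes went with gene length, from a median log2 of -0.21 in the shortest of 5 equal groups of genes above 8 CPM to 0.12 in the longest. The share of reads in no annotated exon was 11.4% ± 0.436 in shSATB1 and 9.10% ± 1.23 in shCtrl. With that share as a covariate, chosen after seeing the data, 858 genes rose and 1262 fell. Of these, 229 changed by 2-fold or more, 121 rising and 108 falling, so most of the excess of 2-fold rises was lost. That share was higher in every shSATB1 library than in every shCtrl library, so the covariate can also absorb part of a group difference. Calls lost or turned with the covariate, here and below, may reflect this overlap. Against a null hypothesis of a 1.2-fold change 758 rose and 698 fell. Rising genes numbered 1662 without shCtrl replicate 3 and 1650 without shSATB1 replicate 3, falling genes 1817 without shSATB1 replicate 1 and 1852 without shSATB1 replicate 3, and 2-fold changes 665 without shCtrl replicate 1 and 211 at a minimum of 1 CPM in 3 libraries.

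Genes of T cell identity moved in both directions. Of 26 tested genes of the T cell receptor complex and proximal signalling, 8 rose and 11 fell (8 and 12 adjusted over the list alone). The phosphatase gene PTPRC (CD45) rose from 502.8 ± 18.8 to 804.7 ± 35.4 CPM, the adaptor gene LCP2 with a log2 fold change of 0.57 (SE 0.0569), the adaptor gene LAT from 9.12 ± 0.426 to 13.5 ± 1.18 CPM, and TRAC, the constant gene of the receptor alpha chain, from 155.6 ± 17.3 to 214.9 ± 8.91 CPM. Of the falls, chosen after their values were seen, TRBC1, a constant gene of the receptor beta chain, went from 634.9 ± 63.0 to 485.1 ± 32.5 CPM, the signalling chain genes CD3D and CD247 from 380.7 ± 46.1 to 308.0 ± 20.7 CPM and from 188.4 ± 4.58 to 159.6 ± 6.05 CPM, and CD5, an inhibitory receptor gene, from 133.4 ± 4.43 to 106.2 ± 4.59 CPM. Of 25 transcription factors of the T lineage, 10 rose and 5 fell (10 and 6 adjusted over the list alone). KLF2, a regulator of lymphocyte trafficking genes, rose from 32.8 ± 3.67 to 60.4 ± 3.84 CPM, ID2 from 3.61 ± 0.790 to 6.93 ± 0.206 CPM and the Notch target HES1 from 3.67 ± 0.360 to 6.64 ± 0.613 CPM. The falls were ETS1, MYB, NOTCH3, STAT5A and GFI1. Of 16 tested loci linked to SATB1 in T cells, 4 rose and 2 fell (4 and 2 adjusted over the list alone). RAG1, a recombinase gene of antigen receptor rearrangement, fell from 82.7 ± 10.6 to 52.4 ± 0.730 CPM, and MYC from 501.7 ± 14.2 to 309.0 ± 9.59 CPM. ZBTB7B (ThPOK), a factor of the CD4 lineage, rose from 3.43 ± 0.651 to 6.93 ± 0.110 CPM, and RUNX3, a factor of the CD8 lineage, from 27.7 ± 0.527 to 34.1 ± 1.63 CPM. The other rises were BCL6 and GATA3. Of 8 tested oncogenic transcription factors of T cell leukaemia, 1 rose and 3 fell (2 and 4 adjusted over the list alone). TAL1 rose from 313.3 ± 7.78 to 493.1 ± 7.60 CPM, and besides MYC the falls were ETV6, from 122.7 ± 4.64 to 88.4 ± 2.53 CPM, and LMO1, from 6.43 ± 0.562 to 4.45 ± 0.529 CPM. The LMO1 call was lost without shCtrl replicate 3 (adjusted p = 0.0540), without shSATB1 replicate 1 (adjusted p = 0.0569) and with the covariate (adjusted p over the alternatives 0.00194 to 0.157, highest with it). None of these lists passed camera, with adjusted p of 0.951 (receptor), 0.235 (lineage factors), 0.831 (SATB1-linked loci) and 0.235 (oncogenic factors).

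NK and cytotoxic markers were higher as a list (camera adjusted p = 1.96e-06, adjusted p = 0.354 with an estimated correlation and 1.77e-08 to 0.000263 over the other alternatives). Of 9 tested members, 4 rose (4 adjusted over the list alone). Besides GZMA these were the pore-forming protein gene PRF1, from 9.75 ± 1.01 to 24.3 ± 2.21 CPM, the transcription factor gene EOMES, from 9.24 ± 0.793 to 18.1 ± 1.37 CPM, and NKG7, from 8.27 ± 0.234 to 11.5 ± 1.05 CPM. Of 22 tested adhesion and migration receptors, 7 rose and 5 fell (7 and 5 adjusted over the list alone). S1PR1, the receptor that guides lymphocyte exit from lymphoid organs, rose from 36.8 ± 1.16 to 100.4 ± 1.47 CPM, and the integrin gene ITGA6 from 32.8 ± 0.842 to 58.3 ± 1.89 CPM. CD99 fell from 444.1 ± 44.0 to 224.9 ± 10.1 CPM and CD34 from 2.94 ± 0.378 to 1.46 ± 0.326 CPM, and both hold the sequence GAAGGAC in the 3′ untranslated region. So does IL2RB, which rose, and 1011 of 11087 coding genes searched carry it there. The other falls were ICAM2, CD1A and CD1E. Of 21 tested cytokines and cytokine receptors, 6 rose and 3 fell (6 and 4 adjusted over the list alone). The interleukin receptor genes IL10RA and IL2RB rose from 5.04 ± 0.961 to 10.6 ± 0.371 CPM and from 5.67 ± 1.17 to 11.9 ± 1.09 CPM, and IL16 from 18.8 ± 1.97 to 29.7 ± 1.23 CPM. The falls were IL32, TNFSF10 and TGFBR2. Adhesion receptors (adjusted p = 0.296) and cytokines (adjusted p = 0.205) did not pass camera, and cytokines passed with the covariate (adjusted p = 0.0416; 0.0416 to 0.450 over the alternatives).

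Immediate early genes were higher as a list (camera adjusted p = 0.00210, adjusted p = 0.450 with an estimated correlation and 2.43e-05 to 0.0460 over the other alternatives). Of 23 tested members, 9 rose (10 adjusted over the list alone). The transcription factor gene JUN rose from 20.1 ± 0.213 to 43.4 ± 2.45 CPM and BTG2, an antiproliferative gene that is also a p53 target, from 29.6 ± 2.34 to 40.5 ± 0.557 CPM. Of 20 p53 target genes, 6 rose (6 rose and 4 fell adjusted over the list alone), among them TP53INP1, from 28.1 ± 1.12 to 56.5 ± 2.82 CPM. Of 25 tested apoptosis regulators, 7 rose and 3 fell (7 and 5 adjusted over the list alone). CFLAR, an inhibitor of caspase-8 activation, rose from 42.7 ± 3.77 to 64.9 ± 1.70 CPM, CASP8 from 136.0 ± 4.33 to 192.1 ± 2.66 CPM and the caspase inhibitor gene XIAP from 62.0 ± 3.90 to 86.8 ± 4.92 CPM. The falls were BAK1, BID and BIRC5. The median log2 fold change of the apoptosis list was -0.03, against a mean of 0.05 and a higher direction by camera. Of 24 genes of the unfolded protein and integrated stress responses, 5 rose and 10 fell (6 and 10 adjusted over the list alone). DDIT4, an inhibitor of mTOR signalling, rose from 20.3 ± 0.726 to 40.5 ± 5.05 CPM, and the other rises were SESN2, PPP1R15A, SEL1L and SLC7A11, the last of which lost the call with the covariate (adjusted p over the alternatives 3.67e-09 to 0.0730, highest with it), whereas HERPUD1 fell from 51.9 ± 3.47 to 36.0 ± 0.356 CPM and SHMT2 from 227.8 ± 15.4 to 162.4 ± 7.93 CPM. Of 25 tested interferon-stimulated genes, 4 rose and 6 fell (4 and 9 adjusted over the list alone). MX2 rose from 13.2 ± 0.936 to 28.0 ± 0.338 CPM, alongside IFIT5, STAT2 and IFIT2, the last of which lost the call with the covariate (adjusted p over the alternatives 0.00378 to 0.0709, highest with it), and the transcription factor gene IRF1 fell from 69.8 ± 2.64 to 46.4 ± 1.59 CPM. Camera gave adjusted p = 0.140 for p53 targets, 0.296 for apoptosis, 0.315 for the stress responses and 0.540 for interferon-stimulated genes. With the covariate p53 targets (adjusted p = 0.0428; 0.0428 to 0.450 over the alternatives) and apoptosis regulators (adjusted p = 0.0270; 0.0270 to 0.554 over the alternatives) passed. The p53 targets also passed with a correction for length and GC content (adjusted p = 0.0460).

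Cell cycle and proliferation genes were lower as a list (camera adjusted p = 3.06e-07, adjusted p = 0.354 with an estimated correlation and 4.93e-08 to 2.38e-06 over the other alternatives). Of 29 members, 17 fell and 2 rose (18 and 2 adjusted over the list alone). The replicative helicase genes MCM7, MCM5 and MCM2 fell from 738.5 ± 32.8 to 480.0 ± 20.3 CPM, from 315.4 ± 7.73 to 209.2 ± 12.4 CPM and from 285.3 ± 9.14 to 191.1 ± 6.03 CPM, and the cyclin gene CCND3 from 451.3 ± 23.3 to 258.9 ± 22.4 CPM. The rises were CDK6, from 1420.1 ± 155.6 to 2080.4 ± 120.8 CPM, and CCNE1, from 11.4 ± 1.43 to 15.2 ± 1.03 CPM. MKI67, at 673.4 ± 137.2 and 720.0 ± 26.2 CPM, and TOP2A, at 807.5 ± 32.2 and 797.8 ± 51.8 CPM, did not pass (adjusted p = 0.543 and 0.867). These 4 genes were chosen after their values were seen. Cholesterol synthesis genes were also lower as a list (camera adjusted p = 5.82e-09, adjusted p = 0.326 with an estimated correlation and 9.61e-11 to 1.32e-07 over the other alternatives). Of 23 tested members, 17 fell (17 adjusted over the list alone). MVD fell from 272.3 ± 8.80 to 179.5 ± 14.2 CPM, FDPS from 388.4 ± 2.51 to 256.5 ± 13.4 CPM and FDFT1, the squalene synthase gene, from 726.8 ± 34.3 to 495.0 ± 9.01 CPM. Glycolysis and hypoxia response genes were lower by camera (adjusted p = 0.00864, adjusted p = 0.491 with an estimated correlation and 0.00338 to 0.190 over the other alternatives), with 13 falls and 2 rises among 28 tested members (13 and 4 adjusted over the list alone). The glycolytic enzyme genes TPI1 and ENO1 fell from 483.0 ± 45.8 to 304.2 ± 12.8 CPM and from 1573 ± 115.1 to 1066 ± 42.8 CPM, while the glucose transporter gene SLC2A3 rose from 16.9 ± 1.06 to 44.2 ± 1.78 CPM, as did PFKFB3. The glycolysis call also ended with the covariate (adjusted p = 0.190).

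Cytosolic ribosomal protein genes were lower as a list (camera adjusted p = 1.22e-12, adjusted p = 0.491 with an estimated correlation and 4.71e-22 to 0.394 over the other alternatives). Of 36 members, 33 fell (34 adjusted over the list alone), with a median log2 fold change of -0.39. RPL8 fell from 1129 ± 127.7 to 756.3 ± 40.8 CPM and RPL3 from 2120.1 ± 208.8 to 1509.7 ± 61.8 CPM. These transcripts are short, and many have near-identical pseudogenes that can share their reads. The camera call held with the correction for length and GC (adjusted p = 4.01e-10) and ended with the covariate (adjusted p = 0.394). Of 13 mitochondrially encoded mRNAs, 1 fell by edgeR, MT-ATP6, from 2834 ± 324.2 to 2414 ± 84.7 CPM. Adjusted over the list alone 0 passed, 3 were at an unadjusted p under 0.05, and DESeq2 and limma-voom each called 1. That call was lost without shCtrl replicate 3 (adjusted p = 0.0719) and without shSATB1 replicates 1, 2 or 3 (adjusted p = 0.114, 0.0933 and 0.181). It was also lost with the correction for length and GC (adjusted p = 0.170), and the direction turned with the covariate (log2 fold change 0.0571; adjusted p over the alternatives 0.000813 to 0.647). The list did not pass camera (adjusted p = 0.540). Replication-dependent histone genes were higher by camera (adjusted p = 0.00210, adjusted p = 0.354 with an estimated correlation and 0.000951 to 0.0289 over the other alternatives), with 4 rises among 9 tested members (4 adjusted over the list alone). HIST1H2BD rose from 2.13 ± 0.472 to 3.64 ± 0.286 CPM, and HIST1H2AC is among the largest rises above. The others were HIST2H2BE, with a log2 fold change of 1.14 (SE 0.208), and HIST1H4H, from 0.316 ± 0.0942 to 1.07 ± 0.263 CPM, both of which lost the call with the covariate (adjusted p over the alternatives 3.63e-06 to 0.107 and 7.53e-05 to 0.528, highest with it). Histone genes have near-identical copies that can share reads.

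Of 20 tested genes of cohesin, CTCF and loop factors, 3 rose and 1 fell (3 and 1 adjusted over the list alone). CDCA5, the cohesin-stabilising factor sororin, fell from 253.4 ± 24.7 to 197.3 ± 0.527 CPM, and the looping factor gene LDB1 rose (log2 fold change 0.26, SE 0.0620). Both lost the call with the covariate (adjusted p over the alternatives 1.4e-06 to 0.279 and 0.00013 to 0.0698, highest with it). NIPBL, the cohesin loader gene, rose from 177.7 ± 26.6 to 217.4 ± 10.6 CPM, and ESCO2, a cohesin acetyltransferase gene, from 45.9 ± 1.08 to 53.9 ± 3.69 CPM. Both lost the call without shCtrl replicate 3 (adjusted p = 0.0781 and 0.107), shSATB1 replicate 1 (0.0919 and 0.0743) or shSATB1 replicate 3 (0.0960 and 0.108), and with the covariate NIPBL turned direction (log2 fold change -0.10). Over the alternatives the adjusted p was 3.8e-05 to 0.440 for NIPBL and 0.00619 to 0.191 for ESCO2, and the call of ESCO2 also ended with the covariate and both calls with the correction for length and GC. Of 20 chromatin partners of SATB1, 1 rose and 2 fell (1 and 2 adjusted over the list alone). SMARCA4, the ATPase gene of SWI/SNF remodelling complexes, fell from 592.0 ± 19.6 to 453.3 ± 15.6 CPM, and SAFB from 328.4 ± 18.9 to 268.0 ± 6.40 CPM, a call that ended with the covariate (adjusted p over the alternatives 0.000105 to 0.225, highest with it). EP300, a histone acetyltransferase gene, rose from 146.1 ± 36.5 to 207.2 ± 6.36 CPM and turned direction with the covariate (log2 fold change -0.10). Of 8 tested clustered protocadherin genes, 0 rose and 0 fell by edgeR (0 and 0 adjusted over the list alone). At an unadjusted p under 0.05 edgeR gave 1, and DESeq2 called 0 and limma-voom 0. PCDHGB6 was at 1.14 ± 0.318 and 1.78 ± 0.154 CPM and passed at a minimum of 1 CPM in 3 libraries (adjusted p = 0.0484) and without shCtrl replicate 1 (adjusted p = 0.0159, and 0.0159 to 0.953 over the alternatives). Camera gave adjusted p = 0.761 for cohesin and loop factors, 0.613 for chromatin partners and 0.581 for protocadherins.

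Of 15 tested Wnt and beta-catenin targets, 5 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.296). The transcription factor gene SOX4 rose from 944.1 ± 17.6 to 1618 ± 136.5 CPM, as did AXIN2, LEF1, TNFRSF19 and CCND1, and NKD2 and MYC fell. TNFRSF19 lost the call with the covariate (adjusted p over the alternatives 0.000174 to 0.0627, highest with it). The CCND1 call was lost without shSATB1 replicate 2 (adjusted p = 0.0616, and 3.01e-05 to 0.0616 over the alternatives). Of 17 tested genes of HLA and antigen presentation, 1 rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.208). The immunoproteasome genes PSMB10 and PSMB9 fell from 18.2 ± 2.10 to 11.5 ± 0.448 CPM and from 39.5 ± 3.05 to 29.6 ± 2.23 CPM, and both lost the call with the covariate (adjusted p over the alternatives 4.28e-09 to 0.104 and 8.02e-06 to 0.344, highest with it). The other falls were HLA-B, HLA-DPA1 and B2M, and the rise was NLRC5. HLA-DPA1 lost the call with the covariate (adjusted p over the alternatives 0.000142 to 0.110, highest with it). The B2M call was lost without shSATB1 replicates 1, 2 or 3 (adjusted p = 0.0701, 0.0614 and 0.0937, and 0.000472 to 0.974 over the alternatives) and with the covariate. Of 4 tested B cell markers, 2 fell (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.613). The kinase gene BLK fell from 15.7 ± 0.365 to 11.6 ± 0.152 CPM and CD79A from 60.5 ± 5.03 to 50.4 ± 4.61 CPM, the latter call being lost without shCtrl replicate 3 (adjusted p = 0.0991), shSATB1 replicate 1 (0.130) or shSATB1 replicate 3 (0.139, and 0.000697 to 0.989 over the alternatives) and with the covariate or the correction for length and GC. Of 6 tested myeloid markers, 1 fell (1 adjusted over the list alone; camera adjusted p = 0.831). AIF1 fell from 72.9 ± 8.39 to 55.1 ± 2.15 CPM, and the call ended with the covariate (adjusted p over the alternatives 9.98e-07 to 0.533, highest with it). Median and mean of the B cell list (0.08 and 0.05) and of the myeloid list (0.10 and 0.06) were positive, while camera gave a lower direction for both. Of 5 tested erythroid and megakaryocyte markers, 1 rose (1 adjusted over the list alone; camera adjusted p = 0.951). The rise was GATA1, from 0.181 ± 0.0934 to 0.495 ± 0.0612 CPM, and its call was lost without shCtrl replicates 2 or 3 (adjusted p = 0.0796 and 0.128) and without shSATB1 replicates 1, 2 or 3 (0.0778, 0.0940 and 0.0685, with 0.0121 to 0.591 over the alternatives), with no filter and with the covariate. This list had a median of -0.03, a mean of 0.20 and a higher direction by camera, with the transferrin receptor gene TFRC at 529.4 ± 17.4 and 519.2 ± 17.1 CPM. Of 6 tested epithelial and packaging-line markers, 1 rose (1 adjusted over the list alone; camera adjusted p = 0.909). NEFM rose from 1.30 ± 0.182 to 2.12 ± 0.0933 CPM, and the call was lost without shCtrl replicate 2 (adjusted p = 0.0557) and without shSATB1 replicates 2 or 3 (0.0629 and 0.0582, with 0.0120 to 0.572 over the alternatives) and with the covariate. VIM was at 198.4 ± 28.5 and 170.8 ± 2.16 CPM and passed with no filter (adjusted p = 0.00833) and without shCtrl replicate 1 (adjusted p = 0.000987, and 0.000987 to 0.278 over the alternatives).

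**Figure D2:**
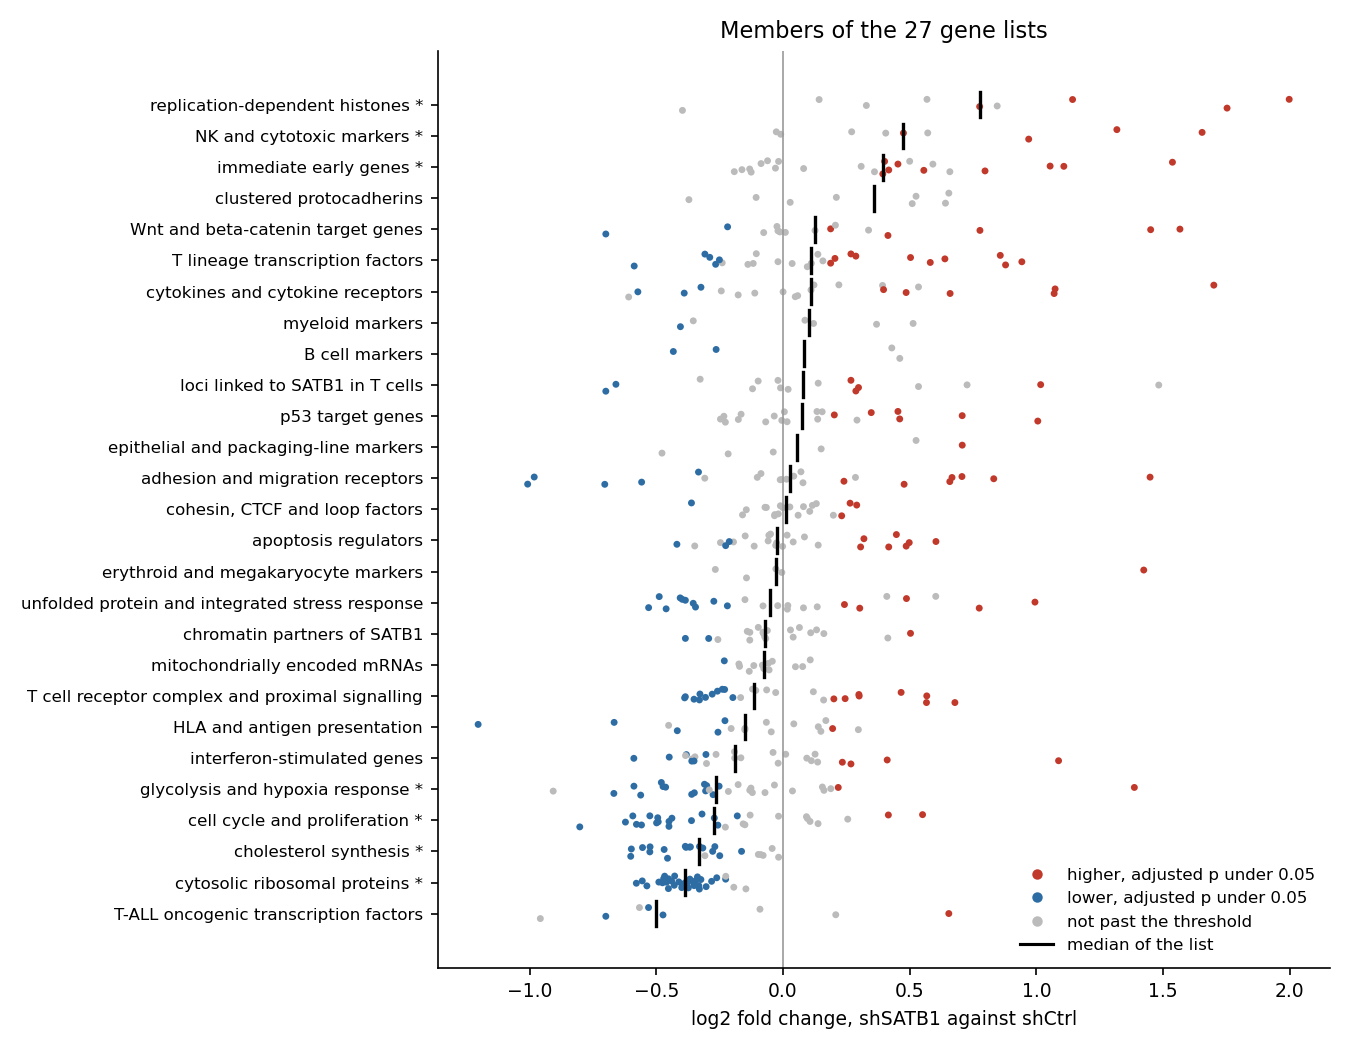
Log2 fold change of shSATB1 against shCtrl (horizontal axis) for each tested member of the 27 gene lists, with list medians as black bars. Points that passed an adjusted p of 0.05 are coloured by direction, grey points did not pass, and asterisks mark the 7 lists past camera's threshold.

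Called genes lay beside each other along the chromosomes more often than permuted calls did, a question raised by the role of SATB1 in chromatin organisation. Among 13208 pairs of adjacent tested genes that did not overlap, both members were called in the same direction in 800, against 656.6 with calls permuted among genes of like expression. The ratio was 1.22 (permutation p = 0.0001, one-sided, the smallest that 10000 permutations can give). For changes of 2-fold or more, 14 such pairs were found against 4.18, a ratio of 3.35 (permutation p = 0.0001) that rests on few pairs. The ratio was 1.28 for pairs within 100 kb and 1.17 among protein-coding genes only (permutation p = 0.0001 for each). For all calls, pairs numbered 397 without shCtrl replicate 3 and 358, 511 and 341 without shSATB1 replicates 1, 2 and 3. With each library left out the ratio lay between 1.17 and 1.35. The CD1 locus on chromosome 1, which encodes lipid-presenting molecules of thymocytes, was chosen after its values were seen. Between 158179947 and 158357553 (hg38), all 5 CD1 genes fell. CD1C fell from 55.7 ± 4.69 to 27.1 ± 1.70 CPM, CD1D from 70.4 ± 4.81 to 38.3 ± 0.960 CPM, CD1B from 88.0 ± 4.05 to 52.7 ± 1.52 CPM, CD1A from 136.0 ± 3.47 to 83.5 ± 2.16 CPM and CD1E from 576.9 ± 26.7 to 391.9 ± 1.57 CPM. Between CD1D and CD1A, the long noncoding RNA AL138899.1 rose from 14.9 ± 5.69 to 29.9 ± 3.76 CPM and the processed pseudogene AL138899.2 from 16.7 ± 2.70 to 24.7 ± 1.05 CPM.

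**Figure D3:**
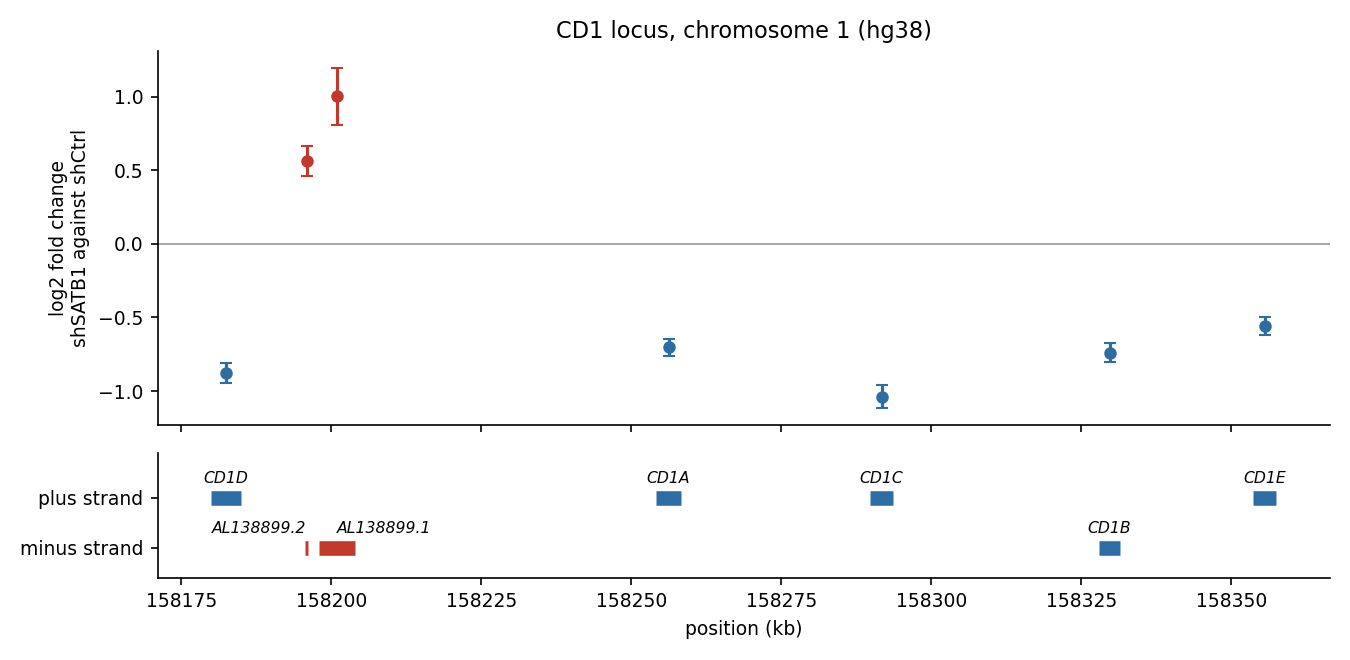
Log2 fold change of shSATB1 against shCtrl with its standard error (top) and position in kb by strand (bottom) for the tested genes of the CD1 locus on chromosome 1. The 5 CD1 genes lie between -1.04 (CD1C) and -0.56 (CD1E), and AL138899.1 and AL138899.2 lie above 0.

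Protein-coding genes made up 88.9% of called genes, against 74.9% of the genes tested (odds ratio 3.67, two-sided Fisher's exact test, p = 1.19e-200). Long noncoding RNAs made up 8.28% of rising and 6.25% of falling genes, against 15.8% of those tested. At a minimum of 1 CPM in 3 libraries the odds ratio of protein-coding genes was 2.51 (two-sided Fisher's exact test, p = 1.41e-76). Neither test matches on expression. Within deciles of mean log2 CPM, a comparison chosen after seeing the data, 87.7% of called genes would be protein-coding by chance, and the odds ratio was 1.24 (95% interval 1.104 to 1.384 by the Mantel-Haenszel method), with differences in expression inside a decile left in place.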

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

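The tests of length slopes per library and of the length and GC correction were chosen only after the result was seen, as was the covariate. Reads in no annotated exon, which enter no comparison of genes, made up more of each shSATB1 library than of each shCtrl library, 11.4% ± 0.436 (SD, n = 3) against 9.10% ± 1.23 (two-sided exact permutation p = 0.1, the smallest possible). Longer transcripts were also higher in shSATB1, with a Spearman correlation of log2 fold change with exonic length of 0.396 across 10228 genes, which are not independent replicates. Differences between pairs of shCtrl libraries went with length as well. Their Spearman correlations were 0.572 (shCtrl 1 minus shCtrl 2), 0.489 (shCtrl 3 minus shCtrl 2) and 0.433 (shCtrl 1 minus shCtrl 3).

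For unspliced RNA in the shSATB1 libraries, summed reads of sense-intronic transcripts, scaled to library size, were 1.07 times those of shCtrl (95% interval 0.969 to 1.18). This lies below the ratio of 1.25 in reads outside exons. The comparison leaves out the spread of that ratio between libraries, so unspliced RNA is not excluded. Genomic DNA cannot be told apart from other sources, because olfactory receptor genes, at 1.12 times (0.928 to 1.36), have too few reads to exclude a ratio of 1.25. A length trend between libraries that is not tied to the knockdown cannot be told apart from one that is: the slope of log2 CPM on log2 exonic length differed by 0.145 between shCtrl 1 and shCtrl 2 and by 0.120 between the group means (95% interval -0.00143 to 0.242, two-sided exact permutation p = 0.1, the smallest possible). That rests on these libraries, since the largest difference within a group was 0.0845 without shCtrl 1 and 0.0603 without shCtrl 2, against 0.154 and 0.0821 between the groups. The length and GC trend as the whole cause of the calls is argued against by 4659 of 5410 genes that stayed called in the same direction once it was removed, whereas with the share outside exons as a covariate 1513 stayed and 6 turned, in a fit where that share separates the groups. An effect of the knockdown on long transcripts stays open, as untested.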

How the results depend on the processing

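The covariate, the length and GC correction and the splits for gene counts were chosen only after the result was seen. SATB1 stayed lower and past the threshold in every alternative run, with log2 fold changes from -1.53 to -1.35. DESeq2 size factors, upper quartile normalization, no filter, DESeq2 and limma-voom kept the counts of rising, falling and 2-fold genes within 1.5 times. DESeq2 called 4988 of the 5410 genes in the same direction, and 4801 remained without shCtrl replicate 2, which stood farthest from its group. Against a 1.2-fold null hypothesis 758 rose and 698 fell, as that null is stricter. With the share outside exons as a covariate, 858 rose, 1262 fell and 229 changed by 2-fold or more. That share separates the groups, so the covariate can absorb part of a group difference. Whether it did was not tested. A filter of 1 CPM in 3 libraries left 211 with 2-fold changes, since fewer genes of low count were tested. Leaving out 1 library gave 1650 to 3218 rising, 1817 to 3562 falling and 300 to 665 2-fold genes; the cause of the rise without shCtrl replicate 1 was not tested. Camera called 7 lists with each library left out and 0 with an estimated correlation (3 at an unadjusted p under 0.05; fry 16). Among 115 named genes other than SATB1, 1619 of 1717 alternative values kept direction and side of the threshold, 87 lost the call and 8 gained it. With the covariate NIPBL (-0.10), EP300 (-0.10) and MT-ATP6 (0.0571) turned direction; the cause was not tested. Depth limits genes near 0.1 CPM, and genes under a filter gave no value for it.

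Whether the replicate numbers pair the libraries stays open. Deviations from the group means correlated at 0.0798, 0.0712 and 0.0032 for equal numbers and between -0.0859 and 0.0157 for unequal ones. However, shCtrl 3 correlated best with shSATB1 1 (0.0157). With the replicate block 2783 genes rose, 3120 fell, 403 changed by 2-fold or more, 7 lists passed camera, SATB1 was at -1.38 and VIM passed (adjusted p = 0.0309).

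The 6 libraries give 10 splits into 3 and 3, too few for a share under 0.05, and only 1 split, the real one, gave counts as large. It gave 2500 rising, 2910 falling and 388 2-fold genes, 7 lists and 800 neighbour pairs. The highest of the other 9 were 0 genes by edgeR (124 to 901 at an unadjusted p under 0.05; other tools were not run), 0 pairs and 6 lists. With 0 genes called, 0 pairs and 0 2-fold genes had to follow, so these counts say nothing on neighbours. Each of the other 9 splits mixes shCtrl and shSATB1 libraries, which widens the spread within its groups and favours 0 calls.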

Other observations

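Of the tests below, those of permutation within bins and within chromosomes, the heptamer on separate chromosomes and with further lengths adjusted, the heptamers below the permuted bound, the spread of other microRNA families and differences within groups were chosen only after the result was seen, as were the genes named here. Runs of at least 4 adjacent tested genes were called upward at 13 places and downward at 22, CD1A to CD1E among the latter. In a run on chromosome 12 (9648047 to 9760901), the lectin gene CLEC2D rose from 6.10 ± 0.391 to 9.41 ± 0.388 CPM and CD69, an early activation marker, from 16.7 ± 1.08 to 26.4 ± 1.23 CPM. In another on chromosome 14 (71320449 to 72894116), RGS6, a regulator of G protein signalling, rose from 0.729 ± 0.245 to 2.00 ± 0.382 CPM and DPF3, a chromatin remodelling subunit gene, from 23.3 ± 0.877 to 44.7 ± 1.28 CPM.

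For the excess of neighbours called in the same direction, read-through between close genes is argued against by a ratio of 1.23 in pairs more than 50 kb apart (one-sided permutation p = 0.0004). That ratio used all calls, and pairs with 2-fold changes were not tested in this way. Shared expression, length and GC of neighbours are argued against only as far as wide bins of these match them. With calls permuted within the bins the ratio was 1.13 (p = 0.0001 by permutation, the smallest 10000 can give), against 1.22 within deciles of expression. Likeness of neighbours inside a bin stays in place, so these traits as the whole cause are not excluded. For whole chromosomes that differ in copy number, the ratio was 1.25 with calls permuted within chromosomes. That permutation left expression unmatched, which can itself raise the ratio, so it cannot decide the question. Median log2 fold changes per autosome and X lay between -0.0571 (chromosome 20) and 0.0509 (chromosome 15). Smaller segments were not tested. An effect of lower SATB1 on genes that lie together stays open, as untested.

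STAU1 and NDUFAB1 fell by more than SATB1, which raised the hypothesis of an off-target effect of the hairpin, whose sequence is not given in the sources used here. All 10 named falls were larger than that of SATB1, so this does not mark out STAU1 and NDUFAB1. A long match was examined for STAU1 and NDUFAB1 alone. A long match cannot be told apart from chance: the longest stretch each mRNA shares with the SATB1 mRNA is 13 bases, and 20.2% (STAU1) and 74.2% (NDUFAB1) of 500 length-matched genes had a shorter one. Among heptamers of the SATB1 mRNA, carriers of GAAGGAC in the 3′ untranslated region had the lowest statistic, with genes compared within deciles of 3′ region length alone or of length and GC together (one-sided permutation p = 0.001 for each, the smallest 1000 can give), but the transcripts searched for STAU1 and NDUFAB1 lack it. With length alone 55 heptamers lay below the 5th percentile of the permuted lowest values, of which the 3′ regions of STAU1 and NDUFAB1 hold 8 and 4, as many or more being found in 60% and 40.2% of 500 genes of like 3′ region length. With length and GC 4 did, GAAGGAC, AAGGACA, AAGGACT and AATAAAG, of which the 3′ region of STAU1 holds 0 and that of NDUFAB1 1 (AATAAAG), so the falls of both genes stay open.

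Because that heptamer was chosen by its statistic, it was chosen again on genes of the odd or the even chromosomes alone and tested on the others, in the same libraries; either choice gave GAAGGAC. On the odd chromosomes, 595 carriers had a mean log2 fold change of -0.0560 (SE 0.0136) relative to genes of like 3′ region length and GC, and on the even ones 416 had -0.0601 (SE 0.0164); all carriers without that adjustment had a median of -0.02, as did other genes (-0.02). Base composition is argued against, as 100% of 139 heptamers of the same bases had a higher statistic in either set of chromosomes. Seed-matched silencing by the hairpin cannot be told apart from other causes. Genes with the heptamer only outside the 3′ region were themselves higher, by 0.0133 (SE 0.00821) and 0.0315 (SE 0.0105), and long transcripts were higher in general. Carriers differed from these genes by -0.0693 and -0.0916, but with exonic length and length outside the 3′ region adjusted as well only by -0.0218 and -0.0450 (one-sided permutation p = 0.0650 and 0.00680). From genes without the heptamer they then differed by -0.0748 and -0.0762 (one-sided permutation p = 1e-05 for each, the smallest 100000 can give). Differences between libraries stay open too, as carriers reached a statistic of 1.895, without sign, between shCtrl 2 and shCtrl 3, against -6.341 between the groups. Carriers called lower numbered 147 on the odd and 108 on the even chromosomes, against 107 and 68.7 expected from genes of like 3′ region length and GC. The further lengths were not adjusted in these counts. The heptamer also lies in the 3′ region of F13A1, LCP2, ZBTB7B, RUNX3, IL2RB, JUN, TP53INP1 and BTG2, which rose.

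A further hypothesis is lower activity of the miR-17 to miR-92 cluster, whose host gene MIR17HG fell from 19.2 ± 2.88 to 13.4 ± 0.895 CPM. With genes compared within deciles of 3′ region length and GC, carriers of miR-19 and miR-92 sites had the highest statistics of 16158 heptamers, 5.07 and 4.81. Those of miR-17 sites had 2.32 and those of miR-18 sites 0.456, on average 1.389, which leaves the cluster open. Differences between libraries cannot be told apart from it for miR-19, whose carriers reached 3.376 between a pair of shCtrl libraries. For miR-92, carriers reached only 1.288 within a group. Such values compare single libraries rather than whole groups, so differences between libraries are not excluded for miR-92 either. Hairpins competing with all microRNAs stay open too: 8 other families had a median of 1.008, with 7 above 0 and miR-181 (2.91), miR-142-3p (2.28) and miR-21 (1.73) highest. Exonic length and length outside the 3′ region were not adjusted for any of these microRNA sites. The general rise of long transcripts is therefore not excluded as a source of these statistics.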
